A study of Mus musculus with 8 samples.

How the data were processed

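RNA was taken from the left ventricles of 8 untreated mice, 1 library per heart, and libraries were made with a stranded poly(A) kit (TruSeq), per the labels' protocols. Reads were aligned with STAR 2.7.1a to GRCm38 (mm10), per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of raw, whole-number counts per Ensembl gene, with no normalization and 1 column per heart. Each column was matched to a sample by its name. Counting without strand would add reads of antisense and overlapping genes to each other, and the handling of reads that map to several places decides the level of pseudogenes and recent gene copies.

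Symbols and positions came from GENCODE M21, which is on the GRCm38 build, and 36345 of the 38293 identifiers matched. Identifiers without a symbol held at most 0.187% of the counts of a library and stayed in the tests. Total counts ran from 11101901 to 14699949 per library. All pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom from 11.5 to 60.0), so each counted as 1 sample.

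Genes were kept by filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, R 4.3.3), with genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over the 13336 genes tested, with a threshold of 0.05, and SE was taken from the log2 fold change and its F statistic. CPM values use TMM-scaled library sizes. The tested genes held 99.9% of counts in each library. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), with fry and with an estimated correlation beside it. Of 42 lists, 39 were large enough. Composition measures were compared by exact two-sided permutation tests over 70 assignments, with the smaller tail doubled, whose smallest p is 0.0286.

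Tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule names Nbdy, then up to 12 genes with the largest rise and 12 with the largest fall among genes that pass, do not overlap between groups and average at least 1 CPM, leaving out pseudogenes and genes without a proper name. It adds 4 members of each called list by p, up to 3 passing members of other lists, the sex-linked genes and Nnt, Nppa, Nppb, Myh6 and Myh7, and Edc4, Dcp1a and Dcp2. Where fewer than 10 genes pass, the 10 with the next smallest p are named as not passing. Ago1 and Gadd45b were named after their values were seen. Some list members that the rule names are not reported here.

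The alternatives were DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, a robust edgeR fit, no filter, a filter of 1 CPM in 4 libraries, removal of mitochondrially encoded genes, 1 surrogate variable (sva 3.50.0), an adjusted p of 0.10, a test against a 1.2-fold change, rank-based camera and each library left out in turn. A fit with a GC content and length trend removed per library (natural splines with 4 degrees of freedom) was added after the data were seen.

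The edgeR test was tested on simulated data with the real genes' means and library sizes and 200 changed genes. Of 13190 genes run for KO against WT, it recovered 29.9% of 1.5-fold, 82.1% of 2-fold and 97.0% of 4-fold changes, with 9 false calls. A simulated 0.8-fold shift of 24 genes of a list was called by camera, also with an estimated correlation (adjusted p = 0.0013), and 0 unshifted lists were called. Each gene was drawn independently, so the simulated lists held no correlation between genes. In the real data that correlation was estimated at 0.443 for ribosomal proteins and 0.536 for immediate early genes. The simulation therefore cannot show how often camera calls unshifted lists, or misses shifted ones, in the real data.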

Results

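Poly(A) RNA from the left ventricle was sequenced in 8 male mice of 8 weeks of age on a C57BL/6 background. GEO's labels give 4 wild-type (WT) hearts and 4 hearts from mice with a knockout (KO) of Nbdy, also called mORF4. Nbdy encodes a microprotein that binds the mRNA decapping complex and takes part in the turnover of processing bodies (P-bodies). Total counts were 12773611, 11101901, 11242809 and 12728039 in WT replicates 1 to 4, and 14699949, 13929706, 13028692 and 11793495 in KO replicates 5 to 8. Of the 38293 gene identifiers in the table, 13336 had enough counts to be tested. The biological coefficient of variation was 0.179, and the median standard error (SE) of a log2 fold change was 0.16.

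Nbdy itself was measured first in every library, as a check of the genotype labels. Its transcript fell to 0.511 of the WT level in the KO hearts and stayed detectable in each of them. WT replicates 1 to 4 held 241, 208, 246 and 248 Nbdy counts, and KO replicates 5 to 8 held 137, 135, 133 and 115. In CPM, counts scaled to library size, this was 19.4 ± 0.470 in WT (SD, n = 4) and 9.92 ± 0.412 in KO (SD, n = 4). Nbdy (ENSMUSG00000086316) lies on chromosome X from 153723590 to 153741920 in GRCm38, on the plus strand, and is annotated as protein-coding. The log2 fold change was -0.97 ± 0.11 (SE), with an adjusted p of 0.0060 in edgeR's quasi-likelihood test. The labels do not describe the KO allele. The counts cover the whole gene, so they do not show whether the allele lacks a part of the transcript. Without KO replicate 6 the log2 fold change was -0.96 and the adjusted p 0.056.

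**Figure D1:**
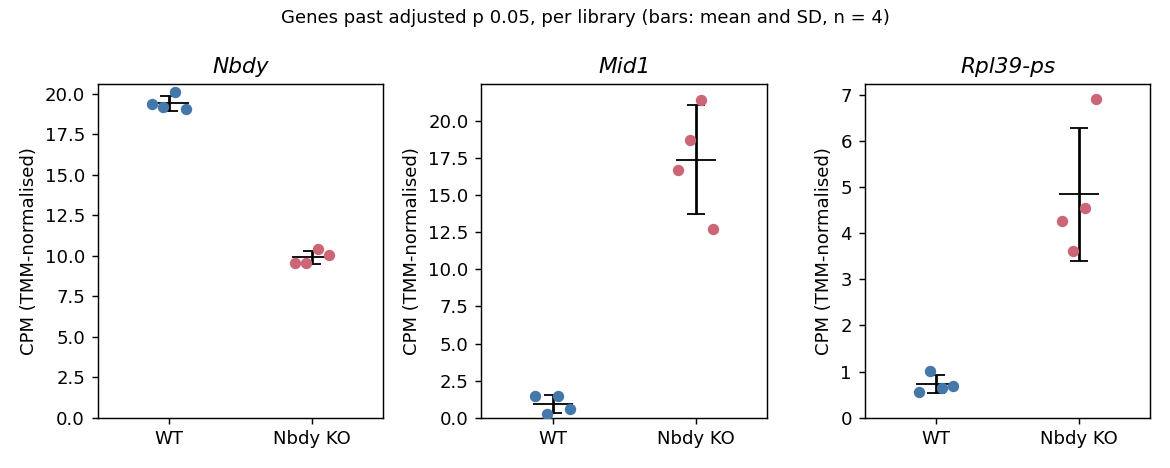
Each point is 1 library, with CPM on the vertical axis and genotype on the horizontal axis; bars give the mean and SD of 4 libraries. The groups do not overlap for Nbdy (19.4 against 9.92 CPM), Mid1 (0.952 against 17.4 CPM) or Rpl39-ps (0.730 against 4.84 CPM).

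The comparison of KO with WT asked how loss of Nbdy alters RNA levels in the left ventricle. Apart from Nbdy, 2 genes passed the threshold, and both were higher in KO. Mid1, a microtubule-associated ubiquitin ligase whose gene crosses the boundary of the pseudoautosomal region in laboratory mice, rose 17.9-fold. Rpl39-ps, a processed pseudogene of the ribosomal protein gene Rpl39, rose 6.58-fold. Nbdy was the 1 gene that fell among those tested. The count filter left out Rps13-ps1 and Gm12840, which passed as lower in KO without a filter. No reference gene of cardiac stress and no gene of the decapping complex passed.

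Mid1 (ENSMUSG00000035299) spans 169685199 to 170005736 on the plus strand of chromosome X. It held 18, 3, 18 and 8 counts in WT replicates 1 to 4 and 238, 263, 273 and 145 in KO replicates 5 to 8. Its level was 0.952 ± 0.601 CPM in WT and 17.4 ± 3.67 CPM in KO (SD, n = 4 each), with a log2 fold change of 4.16 ± 0.33 (SE) and an adjusted p of 2.17e-04 in edgeR. Rpl39-ps (ENSMUSG00000036305) spans 102635038 to 102635188 on chromosome 15. Its counts were 7, 11, 8 and 9 in WT and 61, 51, 58 and 79 in KO, and its log2 fold change was 2.72 ± 0.32 (SE, adjusted p = 0.0060 in edgeR). Rpl39-ps falls outside the rule for named genes and is named because so few genes passed. Its reads can be shared with near-identical copies of Rpl39, so its level is uncertain.

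The 10 genes with the next smallest p did not pass. Klhl38, a muscle-expressed kelch-like gene, came closest, with 6.40 ± 1.26 CPM in WT and 14.9985 ± 3.17 CPM in KO (SD, n = 4 each; log2 fold change 1.22 ± 0.19, adjusted p = 0.087 in edgeR). Chac1, a glutathione-degrading enzyme of the integrated stress response, stood at 1.26 ± 0.22 on the log2 scale, and Gcn1l1, an activator of the kinase Gcn2, at 1.01 ± 0.20. Chac1 passed when adjusted over its list alone, the ATF4 and integrated stress response targets, but that list of 21 genes was not called (median 0.05, mean -0.04, 13 positive and 8 negative, adjusted p = 0.472), and its median was -0.0085 after removal of a GC content and length trend. Mlxip, a glucose-responsive transcription factor, stood at 0.52 ± 0.12 and Tfrc, the transferrin receptor, at -0.52 ± 0.11. Mboat2, a lysophospholipid acyltransferase, had a value of -1.12 ± 0.22, and Mum1l1 on chromosome X a value of -1.33 ± 0.29. The pseudogenes Rps13-ps2, 3110053B16Rik and Gm6472 had values of 0.83 ± 0.15, 1.88 ± 0.41 and -1.75 ± 0.35. The adjusted p of the 9 genes after Klhl38 lay between 0.172 and 0.651. At an unadjusted p under 0.05 there were 853 genes (467 higher and 386 lower in KO), where 666.8 would be found by chance. That count was 662 after removal of a GC content and length trend and 1452 without WT replicate 1. DESeq2 called 8 genes higher and 3 lower, among them Klhl38, Chac1 and Gcn1l1.

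Genes of cardiac stress and contraction showed no difference that passed. Nppa, the atrial natriuretic peptide gene, had 400.2 ± 96.4 CPM in WT and 601.2 ± 123.4 in KO (SD, n = 4 each; log2 fold change 0.59 ± 0.19, adjusted p = 0.711 in edgeR). Nppb, the B-type natriuretic peptide gene, had a log2 fold change of -0.84 ± 0.47, but WT replicate 2 alone held 1209 CPM, and without that library the value was 0.09. Myh6, the main adult myosin heavy chain, had 21837 ± 1465 CPM in WT and 23407 ± 2571 in KO (log2 fold change 0.10 ± 0.14; -0.04 after removal of a GC content and length trend). Myh7, the slow myosin heavy chain, varied so much within both groups that its log2 fold change of -0.09 had an SE of 0.76. Of the 20 measured genes of the cardiac stress and fetal list none passed, and camera did not call the list (median log2 fold change -0.14, adjusted p = 0.073). Rank-based camera called it lower (adjusted p = 0.040), as did the fits without WT replicate 1, WT replicate 3 or KO replicate 7 (0.019, 0.012 and 0.014), while without WT replicate 2 the median was 0.03. The 26 sarcomere genes had a median of -0.05 (adjusted p = 0.961), but without WT replicate 2 the median was 0.093 and the list was called higher (adjusted p = 0.042).

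The decapping genes that Nbdy's protein is linked to showed no difference between genotypes that passed. Edc4, the scaffold of the decapping complex, had a log2 fold change of 0.16 ± 0.12, the decapping enzyme gene Dcp2 0.18 ± 0.16 and its activator gene Dcp1a 0.13 ± 0.12. None of these 3 genes passed, with adjusted p of 0.820, 0.858 and 0.865 in edgeR. Edc4 ran from 0.05 to 0.23, Dcp2 from 0.09 to 0.28 and Dcp1a from 0.07 to 0.19 over the alternative fits. Of 34 P-body and decapping factors 0 passed, over all genes or adjusted over the list alone (median 0.04, adjusted p = 0.458 by camera). Their median was 0.107 without WT replicate 1 and turned to -0.020 without WT replicate 4. Among these factors Ago1, an Argonaute protein of small-RNA silencing, had the smallest unadjusted p (log2 fold change 0.44 ± 0.15, adjusted p = 0.725 in edgeR). The 27 factors of the CCR4-NOT deadenylase and of nonsense-mediated decay had a median of -0.04 (adjusted p = 0.612). The 19 reported targets of nonsense-mediated decay had a median of -0.11 (adjusted p = 0.458 by camera). With 1 library left out, that median ran from -0.193 (WT replicate 4) to -0.026 (WT replicate 3). Gadd45b, a stress-induced gene of that list, passed when adjusted over the list alone (1.07 ± 0.27) and not over all genes (adjusted p = 0.652 in edgeR); with 1 surrogate variable it passed over all genes as well (log2 fold change 1.41, adjusted p = 0.012).

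Across 39 gene lists fixed before the data were examined, camera with its preset correlation called 6 lower and 5 higher in KO. With the correlation estimated from the data, 0 lists were called, and the smallest adjusted p was 0.885. Fry called 0 lists in one direction (smallest adjusted p 0.489) and 2 in either direction, the histones and a list of Nbdy with genes near it on chromosome X, which holds the targeted gene itself. Apart from Nbdy, no member of any list passed over all genes in the main fit. In alternative fits Chac1 passed with DESeq2 and without a filter, Nr1d1 with DESeq2 and Gadd45b with 1 surrogate variable.

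The lists of the unfolded protein response, of ribosomal proteins and of heat shock proteins were lower, and the 44 translation initiation and elongation factors were not called (median 5.46e-04, 22 positive and 22 negative, adjusted p = 0.944). The unfolded protein response of the endoplasmic reticulum had a median log2 fold change of -0.13 over 20 genes, 17 of them negative (adjusted p = 0.0028, and adjusted p = 0.885 with an estimated correlation). Its chaperones Hspa5 (-0.47 ± 0.14), Pdia3 (-0.32 ± 0.11) and Hsp90b1 (-0.28 ± 0.12) were below every WT library in all 4 KO libraries, and Creld2 stood at -0.32 ± 0.16. These members were named for their small p, so their separation adds no support to the list. Over all genes tested, 4.12% had groups that do not overlap in either direction, against 2.86% by chance. The 79 cytosolic ribosomal protein genes had a median of -0.10, with 64 negative (adjusted p = 0.0022, and adjusted p = 0.885 with an estimated correlation). Rpl35 (-0.35 ± 0.12), Rpl38 (-0.43 ± 0.15) and Rpl41 (-0.28 ± 0.12) lay with the list, and Rps16 lay against it at 0.33 ± 0.13. The 20 cytosolic heat shock genes had a median of -0.18 (adjusted p = 0.019, and adjusted p = 0.885 with an estimated correlation), with Hsp90aa1 at -0.66 ± 0.23, Dnajb1 at -0.43 ± 0.20, Hspa1a at -1.71 ± 0.86 and Hspa1b at -1.25 ± 0.71. Over the alternative fits Dnajb1 ran from -0.59 to -0.17 (without WT replicate 3), Hspa1a from -2.61 (without KO replicate 8) to -0.60 (with 1 surrogate variable) and Hspa1b from -1.95 (without KO replicate 8) to -0.61 (with 1 surrogate variable). The values of Creld2, Hsp90b1 and Rpl41 reached -0.18, -0.17 and -0.17 at the weak end. None of these members passed over all genes or adjusted over the list alone. Without WT replicate 2 the medians of the ribosomal protein and heat shock lists were -0.02 and -0.01, and both had an adjusted p of 0.349. Both calls also ended without KO replicate 6 (adjusted p of 0.051 and 0.078), and the heat shock call ended without KO replicate 7 (adjusted p of 0.094).

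The immediate early genes, which respond to acute stimuli within minutes, were lower as a list, with a median of -0.29 and 21 of 26 members negative (adjusted p = 0.0034, and adjusted p = 0.885 with an estimated correlation). Fosl2 had a log2 fold change of -0.44 ± 0.16, Ccn1 of -0.80 ± 0.39 and Egr2 of -1.05 ± 0.54. Over the alternative fits Ccn1 ran from -1.09 to -0.30 and Egr2 from -1.79 to -0.50; WT replicate 2 held 404.6 CPM of Ccn1, and without it the value was -0.35. Atf3 stood at -2.32 ± 0.91, and at -0.06 without WT replicate 2, where it reached 260.5 CPM against 5.94 to 23.8 in the other WT libraries. No member passed over all genes or adjusted over the list alone. The call ended without WT replicate 2 (median -0.16, adjusted p = 0.226), without KO replicate 5 (adjusted p = 0.159) and without KO replicate 6 (adjusted p = 0.077). With 1 library left out, the median ran from -0.135 (KO replicate 5) to -0.667 (KO replicate 7, adjusted p = 7.71e-14).

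The lists of fasting response, core clock and fatty acid oxidation were higher. The lists of glycolysis and glucose uptake (median 0.02, adjusted p = 0.612) and of nuclear-encoded oxidative phosphorylation (median -0.02, adjusted p = 0.844) were not called; the latter was called lower without WT replicate 1 (median -0.095, adjusted p = 0.012) and higher without WT replicate 2 (median 0.056, adjusted p = 0.042). The 21 glucocorticoid and fasting responsive genes had a median of 0.12 (adjusted p = 0.019, and adjusted p = 0.885 with an estimated correlation). The muscle ubiquitin ligase Fbxo32 (0.63 ± 0.16) passed when adjusted over the list alone, and the clock gene Per1 (0.34 ± 0.11) and Txnip (0.31 ± 0.15) did not. The 21 genes of the core clock and its output had a median of 0.21 (adjusted p = 0.019, and adjusted p = 0.885 with an estimated correlation). The clock repressor Nr1d1 (0.61 ± 0.14) passed when adjusted over the list alone, and Nfil3 lay against the list at -0.996 ± 0.44. WT replicate 2 held 36.7 CPM of Nfil3 against 6.45 to 11.6 in the other WT libraries, and without it the value was -0.15. The 34 fatty acid oxidation genes had a median of 0.08 (adjusted p = 0.026, and adjusted p = 0.909 with an estimated correlation), with Cpt1b at 0.73 ± 0.26, Pnpla2 at 0.38 ± 0.15 and Ucp3 at 0.80 ± 0.38. KO replicate 5 held the most Cpt1b and Ucp3 of the KO libraries (21.1 and 150.6 CPM), and without it their values were 0.40 and 0.52. Per1 and Txnip reached 0.19 and 0.18 at the weak end of the alternative fits. Each of these 3 calls ended without WT replicate 1 (adjusted p of 0.239, 0.226 and 0.172) or KO replicate 8 (0.086, 0.459 and 0.086), the fasting call also without WT replicates 3 or 4 or KO replicate 7 (0.081, 0.069 and 0.057), the clock call without WT replicate 4 (0.201), and the fatty acid call without WT replicate 3 or KO replicate 5 (0.499 and 0.503). With 1 library left out, the medians ran from 0.032 (WT replicate 4) to 0.354 (WT replicate 2) for fasting genes, from 0.033 (KO replicate 8) to 0.275 (KO replicate 6) for clock genes and from 0.015 (KO replicate 5) to 0.202 (WT replicate 4) for fatty acid oxidation.

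Mitochondrially encoded genes were higher as a list, with all 8 tested members positive and a median of 0.26 (adjusted p = 0.019, and adjusted p = 0.885 with an estimated correlation). The respiratory chain genes mt-Nd4 (0.40 ± 0.21), mt-Cytb (0.30 ± 0.17) and mt-Nd5 (0.40 ± 0.28) did not pass. The value of mt-Nd6 was 0.74 ± 0.44, and -0.15 without KO replicate 5. Over the alternative fits mt-Nd4 ran from 0.27 to 0.66, mt-Cytb from 0.22 to 0.46 and mt-Nd5 from 0.25 to 0.85. Mitochondrial transcripts took 22.1 ± 4.77% of counts in WT and 24.4 ± 1.64% in KO (SD, n = 4 each), which did not differ by an exact two-sided permutation test (p = 0.400, adjusted p = 0.549 over 6 composition measures). WT replicate 1 held 29.2% and the other WT libraries 19.4 to 19.9%; without it the difference was 4.70 percentage points (exact p = 0.057 with the smaller tail doubled, which is the smallest that definition can give for 4 against 3 libraries, and exact p = 0.029 by the absolute difference, a definition added after the data were seen). Of the 13 mitochondrial protein-coding genes, 6 had at most 400 counts in every library, so this share covers only part of the mitochondrial RNA. The list's call ended without WT replicate 3, WT replicate 4 or KO replicate 5 (adjusted p of 0.130, 0.156 and 0.150), and its median ran from 0.14 without KO replicate 5 to 0.46 without WT replicate 1.

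Markers of blood were higher as a list, with a median of 0.15 over 9 genes (adjusted p = 0.036, and adjusted p = 0.885 with an estimated correlation). The heme synthesis gene Alas2 stood at 0.49 ± 0.19, the globin genes Hbb-bt at 0.57 ± 0.28 and Hbb-bs at 0.31 ± 0.26, and the platelet gene Ppbp at 0.50 ± 0.35. Over the alternative fits Hbb-bt ran from 0.29 to 0.72, Hbb-bs from 0.11 to 0.50 and Ppbp from 0.24 to 0.75. Haemoglobin genes took 0.136 ± 0.0449% of counts in WT and 0.159 ± 0.0384% in KO (SD, n = 4 each; exact permutation p = 0.457). The blood call ended without WT replicate 1, WT replicate 3, KO replicate 5 or KO replicate 7 (adjusted p of 0.335, 0.088, 0.354 and 0.119), and its median ran from 0.097 without WT replicate 1 to 0.388 without WT replicate 2. Markers of fibroblasts (median -0.11, adjusted p = 0.073), endothelium (-0.02, adjusted p = 0.832), macrophages (-0.04, adjusted p = 0.746), lymphocytes (-0.21, adjusted p = 0.391) and atrium (0.14, adjusted p = 0.284) were not called. The fibroblast list was called lower after removal of the GC content and length trend (adjusted p = 0.027) and without WT replicate 1, WT replicate 3 or KO replicate 7 (0.034, 0.021 and 0.012), and its median was 0.01 without WT replicate 2. The lymphocyte list was called lower without KO replicate 7 (median -0.455, adjusted p = 0.018), and its median was -0.036 without KO replicate 8.

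Of the 37 genes of the replication-dependent histone list, 7 had enough counts to be tested. These 7 were lower as a list (median -0.17, adjusted p = 0.036 by camera, and adjusted p = 0.885 with an estimated correlation). Poly(A) libraries measure only polyadenylated histone transcripts, so the list does not measure histone RNA as a whole. Hist1h4i (-1.67 ± 0.41) passed when adjusted over the list alone, at low means of 2.05 CPM in WT and 0.631 CPM in KO. Hist1h2be (-0.34 ± 0.23) and Hist2h2be (-0.17 ± 0.17) did not pass. H1f0 (-0.24 ± 0.11) is known as a linker histone whose expression does not need replication, although the list holds it. The histone call ended with rank-based camera (adjusted p = 0.192), after the GC content correction (0.086) and without WT replicate 2, WT replicate 4, KO replicate 5 or KO replicate 8 (0.096, 0.433, 0.133 and 0.086). With 1 library left out, its median ran from -0.067 (KO replicate 7) to -0.231 (KO replicate 6). The sex-linked control genes were also lower as a list of 5 (median -0.28, adjusted p = 0.036, and adjusted p = 0.885 with an estimated correlation). The Y-linked genes Ddx3y, Eif2s3y and Uty stood at -0.30 ± 0.15, -0.28 ± 0.17 and -0.23 ± 0.20, Kdm5d at 0.01 ± 0.18, and the X-linked antisense gene Tsix at -0.93 ± 0.52. The value of Kdm5d was negative in 5 of 18 alternative fits, such as -0.04 with scaling by library totals. Over those 18 fits Ddx3y ran from -0.45 to -0.17, Eif2s3y from -0.38 to -0.14, Uty from -0.42 to -0.12 and Tsix from -1.43 to -0.59. The sex-linked call ended after the GC content correction (adjusted p = 0.167) and without WT replicate 1, WT replicate 3, KO replicate 5, KO replicate 7 or KO replicate 8 (0.172, 0.195, 0.067, 0.072 and 0.067), and its median ran from -0.172 without KO replicate 5 to -0.422 without WT replicate 4. Xist had 0 to 3 counts in every library, all from mice labelled male. The substrain control Nnt was present in all 8 libraries (2392 to 4282 counts, log2 fold change -0.15 ± 0.18).

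**Figure D2:**
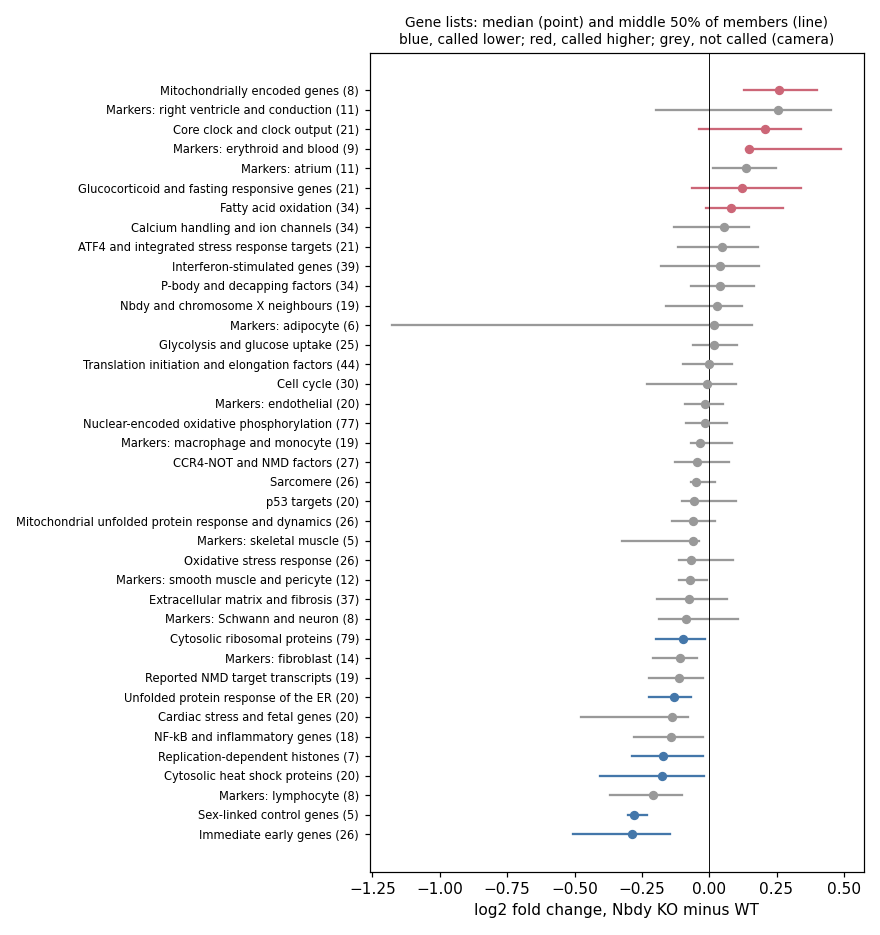
Each row is 1 gene list with its number of tested genes; the point is the median log2 fold change of KO against WT and the line spans the middle 50% of members. Medians of the called lists run from -0.29 for immediate early genes to 0.26 for mitochondrially encoded genes, and 0 lists were called with an estimated correlation.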

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

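The search for single libraries far from the others, the splits of the libraries and the fits without 1 library were planned; the GC content and length correction, and the bounds by which the splits and the fit without WT replicate 2 were read as tests of an explanation, were chosen after the result was seen. In 14 of 144 groups of 4 libraries, 1 library stood far from the other 3, where chance gives about 1 in 20, or 7.2. That rate holds for independent, normally distributed values. The values here were CPM without a log scale, of related genes in the same 8 libraries, so 14 against 7.2 cannot show an excess. In WT replicate 2, Nppb stood at 1209 CPM against 246 to 285 in the other WT libraries, Atf3 at 260.5 CPM against 5.94 to 23.8, and Hsp90b1 at 286.6 CPM against 227 to 233. WT replicate 1 held 29.2% mitochondrial counts and 32075 CPM of mt-Nd5, against at most 14805 CPM in the other WT libraries. KO replicate 5 held 498.8 CPM of mt-Nd6 against 97.0 to 121 in the other KO libraries, 51.2 CPM of Eif2s3y and 3.08 CPM of Ppbp. KO replicate 8 stood high for Hspa1a (14.96 CPM), Hsp90aa1 (40.1 CPM) and Txnip (851.8 CPM). Mboat2 stood high in KO replicate 6 (4.19 CPM), Hsp90b1 low in KO replicate 7 (179.2 CPM) and Dcp1a low in WT replicate 4 (17.7 CPM).

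The lists called by camera were the first pattern weighed. Of the 35 splits of the 8 libraries into 4 and 4, 18 called at least as many lists as the real split, with the real split among the 18. It called 11 lists and the highest other split 21, so chance cannot be excluded. The log2 fold changes correlated with GC content across genes (Spearman rho 0.334, over genes that are not independent replicates). With libraries as the unit, the log2 slope per 10% of GC content averaged -0.055 in WT and 0.055 in KO. This difference did not pass an exact permutation test that was not among those planned (p = 0.086). Removal of a GC content and length trend left 9 of the 11 called lists called, which argues against that trend as their whole cause. It also called the fibroblast and the extracellular matrix lists lower (adjusted p of 0.027 and 0.0084 by camera). Of the histone and sex-linked lists 0 stayed called (medians from -0.17 to -0.07 and from -0.28 to -0.14), and since they were set apart by this outcome the GC content trend stays open for them. Without WT replicate 2, 7 of the 11 lists stayed called and 0 of the ribosomal protein, heat shock and immediate early lists, whose medians moved toward 0, so that 1 heart may carry part of those 3 shifts.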

How the results depend on the processing

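No paired analysis was possible because the groups share no replicate numbers. The GC content and length correction and the p from the absolute difference were chosen after the data were seen. Mid1 and Rpl39-ps passed in all 18 alternative fits, with adjusted p of at most 0.0037 and 0.047. The targeted gene Nbdy kept its direction throughout and lost the threshold only without KO replicate 6 (log2 fold change -0.96, adjusted p = 0.056, fewer samples); leaving out each library gave -0.995 to -0.953. The count of genes higher was 8 with DESeq2, 6 without a filter and 4 with 1 surrogate variable, and 2 to 5 with each library left out. The count of genes lower was 3 with DESeq2, 4 without a filter, and 0 to 3 with each library left out. The lists called fell to 0 with an estimated correlation, and were 5 to 14 with each library left out. The mitochondrial share without WT replicate 1 (4.70 percentage points higher in KO) passed by the absolute difference (exact p = 0.029) and not with the smaller tail doubled (0.057), which follows from the definitions; no other library left out made it pass. Log2 fold changes turned sign for Kdm5d with library totals (-0.038), 1 surrogate variable (-0.079) and single libraries left out (-0.094 to 0.117), and for Myh7 with limma-voom (0.22), 1 surrogate variable (0.038) and single libraries left out (-0.488 to 0.280). They turned for Myh6 after the GC content correction (-0.039), for Nppb without WT replicate 2 (range over libraries left out -1.06 to 0.089) and for mt-Nd6 without KO replicate 5 (range -0.152 to 0.979). None of these passed in any setting, and the cause was not tested. Depth limits genes near 1 CPM, such as Mid1 in WT.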

Other observations

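The splits of the libraries and the alternative fits were planned; the bound by which the splits were read, and all other tests in this part, were chosen after the result was seen. Of the 35 splits of the 8 libraries, 4 called at least as many genes as the real split, with the real split among the 4. It called 3 genes and the highest other split 6, so chance cannot be excluded for that count. At an unadjusted p under 0.05, 7 of the 35 splits, the real one included, had at least as many genes as the real one (853, highest other split 1445). On chromosome X lay 3 of the 10 genes with the smallest p, Mid1, Nbdy and Gm6472, against 3.33% of the genes tested. Nbdy is the targeted gene, so 1 of these 3 is there by design and does not count toward an excess on chromosome X. Gm6472, 0.813 Mb from Nbdy, held 59, 50, 56 and 56 counts in WT and 34, 14, 18 and 6 in KO. It did not pass in the main fit, and it passed with DESeq2 and without a filter. Ribosomal protein pseudogenes other than Rpl39-ps and Rps13-ps2 had a median log2 fold change of 0.09, and 17 of 29 were positive.

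Some genes had separate high and low levels among the hearts, in both genotypes. A rule set after the data were seen asked for a gap of more than 5-fold, with 1 added to each normalised count. It also asked for 2 or more libraries on each side and at least 20 normalised counts at the top. By this rule 30 of 21572 genes did so, 13 of them high in 5 or 6 libraries, and 25 were high in libraries of both genotypes. The rule takes in genes near the floor, such as Ptx3, with 0, 20, 5 and 7 counts in WT and 6, 0, 10 and 6 in KO. Trim6, a ubiquitin ligase of interferon signalling, held 613 counts in WT replicate 2 and 262 in KO replicate 6, and 9 to 26 in the other 6 libraries. The myosin gene Myh7 held 793 counts in WT replicate 3 and 2120 in KO replicate 6, and 18363 to 21076 elsewhere. The imprinted gene Zrsr1 held 219, 285 and 216 counts in WT replicate 2, KO replicate 5 and KO replicate 8, and 2329 to 7110 elsewhere. The fatty acid elongase gene Elovl7 held 0, 3 and 3 counts in WT replicate 3, KO replicate 5 and KO replicate 7, and 46 to 70 elsewhere, while the interferon-inducible gene Ifi202b held 48, 48 and 30 counts in WT replicates 1 and 2 and KO replicate 5, and 0 elsewhere. The pseudogene Rps13-ps1 held 815, 917 and 731 counts in WT replicates 2 to 4 and at most 2 elsewhere. The estrogen receptor gene Esr1 held 125 and 185 counts in WT replicates 1 and 4 and 7 to 20 elsewhere.

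The 30 genes had 24 distinct patterns of high libraries, which argues against a library-wide difference such as mixed libraries, another tissue or a batch. Genes near the floor, such as Ptx3, add to that count of patterns. Tables simulated with the average dispersion fitted at each expression level held at most 1 such gene in 20 draws. Such tables hold no gene more variable than that average, so they cannot show whether the 30 genes exceed their own variability. A candidate explanation is that variants segregate among the animals, as in a mixed strain background. Of 3 pairs of such genes within 10 Mb of each other, 0 shared their pattern, and so few pairs leave variants that segregate open. Reads shared between copies were not tested and stay open for the 12 pseudogenes, and genotype was not tested as an explanation. Genotype alone does not give the patterns of the 25 genes that were high in libraries of both genotypes. Apart from Mid1, 4 of the genes were high in 1 genotype only, in WT: Rps13-ps1 and Gm12840 in 3 of 4 WT libraries, and Esr1 and Gm12696 in 2 of 4. The count filter left Rps13-ps1 and Gm12840 out of the main fit. Both passed as lower in KO without a filter and without WT replicate 1, so an effect of genotype stays open for the 4 genes high in WT only.

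Mid1 lies 15.9 Mb from Nbdy on chromosome X, so a segment linked to the targeted allele may differ between the genotypes. Of the 50 genes tested between Nbdy and Mid1, 4% had an unadjusted p under 0.05, against 6.39% of other genes (Fisher's exact p = 0.770), and with an upper 95% bound of 13.7% a linked segment cannot be told apart from none. Hccs, in that interval near Mid1, held 456, 469, 470 and 388 counts in WT and 369, 378, 340 and 309 in KO. Its counts were lower in each KO library than in any WT library. Groups that do not overlap were found for 4.12% of all genes tested, so Hccs alone decides nothing. Within 5 Mb of Nbdy, with Nbdy itself left out, 5 of 32 genes (15.6%) had an unadjusted p under 0.05, against 6.36% of genes outside. Fisher's exact p was 0.0503, and adjusted over the 2 regions it was 0.101 here and 0.770 for the interval toward Mid1. Those 5 genes hold Alas2, named above as a blood marker, and Gm6472, whose values were seen before the window was set. The count therefore cannot decide on a segment linked to Nbdy. Of those 5 genes 0 lay in the interval toward Mid1, where 8 of the 32 are. A copy gain that spans Mid1 and its neighbour Gm21887 would put Gm21887 high in every KO library if its reads were counted in full. Gm21887 was above every WT library in 2 of 4 (96, 152, 3 and 12 counts in KO replicates 5 to 8, and 2, 9, 28 and 4 in WT). The counts are few, and how reads that match both X and Y near the pseudoautosomal boundary were counted is not given. A copy gain therefore stays open. G530011O06Rik, within Mid1 and under the same limits, held 12, 11, 8 and 9 counts in WT and 0, 2, 9 and 0 in KO. An effect of Nbdy loss on Mid1, and a variant at Mid1 itself, both stay open and untested.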
